A study of Mus musculus with 8 samples.

How the data were processed

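RNA was measured in 8 libraries of mouse adult cardiomyocytes, 4 of single colored and 4 of double colored cells. Per the labels, RNA was isolated with the miRNeasy Micro Kit and libraries were made with the Ovation RNA-seq System v2, which amplifies small amounts of RNA. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, reads were aligned to the mouse genome build mm9 with STAR 2.5.2b and counted with featureCounts of the Subread package. Alignment file names in the file headers point to alignments restricted to chromosomes and to a mapping quality of 30. The strand setting of the counting is not given in the sources used here, so reads of a gene and an overlapping antisense gene cannot be told apart.

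The deposited table lists 37991 Ensembl genes. Its values are whole raw read counts, not estimated counts, per the file headers, and nothing was rounded. The same table holds CPM that the authors recalculated with edgeR after marking 22276 genes as too low and 4 as too high, per the file headers. These deposited values matched each raw count over the total of the kept genes within 0.005. The authors' deposited log2 fold changes run from single to double colored cells, opposite to those given here, and come with deposited p-values and Benjamini-Hochberg FDR values from a test that is not given in the sources used here. Across 12462 genes tested in both, which are not independent replicates, the median absolute difference between the authors' deposited log2 fold changes, with the sign turned, and those computed here was 0.00898.

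Gene symbols were matched by Ensembl identifier to GENCODE vM21 names for 32919 genes, and 5072 kept their identifier. Coordinates are those of the deposited table in mm9, from the first exon start to the last exon end. Exon overlap between genes was computed from the same coordinates with GenomicRanges 1.54.1.

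The count test was edgeR 4.0.16 in R 4.3.3 on the raw counts of all 8 libraries. Genes were kept by filterByExpr with its default minimum count of 10, libraries were scaled with TMM factors, which ran from 0.733 to 0.972 in double and from 0.953 to 1.44 in single colored libraries, and groups were compared with the robust quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05 over 12466 genes. Fold changes are log2 of single over double colored cells with a standard error derived from the F statistic. CPM values use the TMM factors and are given as mean ± SD (n = 4).

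Gene lists, 23 in all with at least 3 tested members, were compared with limma 3.58.1 on TMM log2 CPM with a prior count of 2. The main list test was camera with a preset correlation of 0.01, and camera with an estimated correlation and fry were run beside it, each adjusted over the lists. Per library, the mean log2 CPM over a list's members was compared by an exact permutation test, two-sided, over all 70 groupings, whose smallest p is 0.0286. This test ignores the replicate numbers, and the same test within the numbered pairs, added after the results were seen, has a smallest p of 0.125. The test was tried on simulated data with the means, library sizes and dispersion of these libraries and 200 changed genes among 12466. Of genes changed by 1 on the log2 scale 39% were called, and of those changed by 2, 82%. Of 128 calls 7 were false, and no list was called. Simulated genes were drawn independently and without an effect of the numbered pairs. The simulation therefore does not test list calls where genes vary together, and other splits of the real libraries gave up to 17 lists by camera.

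The named genes were fixed by rule before the data were examined. They are the 4 injected genes, the 12 genes in each direction with the largest absolute log2 fold change among those past the threshold with no overlap between groups (leaving out predicted genes and small RNAs), and in each list up to 4 members with the smallest p. The test, the lists and most alternatives were fixed at the same time. For Acp5, Dhrs9 and Slc7a11, which had few reads in double colored cells, the ratio of group rates is given with an exact conditional binomial 95% interval.

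The groups share replicate numbers. Deviations of same-numbered libraries from their group means correlated across genes by 0.257, 0.126, 0.136 and 0.139 for numbers 1 to 4, each above its highest correlation with another number (at most 0.108). By the rule used here, that every pair lies above 0.1, the numbers were taken to pair the libraries. The highest correlation with another number, 0.108, also lies above 0.1, so this cutoff alone does not separate pairs from other combinations. In the sample descriptions same-numbered libraries also share an id and have neighboring barcodes, 8 and 9, 10 and 11, 12 and 13, and 14 and 15. The labels do not say what a number marks, so the pairing rests on the correlations and on these ids. The main fit has no block, and values with the number as a block are given where they change a call. Counts of libraries of a group differed by 10.4 to 79.3 times the sampling variance per gene, which leaves open whether they were separate animals or separate amplifications of one RNA.

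Alternatives fixed beforehand were other scalings (RLE, upper quartile, library totals), other filters (no filter, or 5 CPM in 4 libraries), DESeq2 1.42.0, limma-voom with quality weights, a non-robust fit, the replicate block, the library total as a covariate, omission of mitochondrially encoded genes, limma on the deposited CPM with a pseudocount of 1, and omission of each library in turn. Chosen after seeing the data were thinning to 3503353 nuclear-encoded reads, restriction to the genes the authors kept, omission of both libraries numbered 1, and 14 combinations of test, scaling and block tried on the authors' kept genes while comparing with their p-values.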

Results

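RNA sequencing was carried out on adult cardiomyocytes, the contractile muscle cells of the heart, isolated from mouse hearts that had received adenoviruses carrying 4 cell cycle genes. The mice carried a tamoxifen-activated Cre recombinase driven by the alpha myosin heavy chain promoter, together with the MADM (mosaic analysis with double markers) reporter. In MADM, recombination between homologous chromosomes followed by division can leave daughter cells with a single fluorescent color, while cells that have not divided this way can carry both colors. Cells were collected 2 weeks after injection as single colored cells (4 libraries), which the labels describe as having gone through the cell cycle, and as double colored cells (4 libraries), described as treated alike without having done so. The libraries held between 23820700 and 30082278 counted reads over 37991 genes. Mitochondrially encoded genes took 82.4% ± 3.97 (SD, n = 4) of the reads in single colored libraries and 86.5% ± 1.88 (SD, n = 4) in double colored libraries (exact permutation test, two-sided, p = 0.143). This left 4795020 ± 1033485 and 3665666 ± 171838 nuclear-encoded reads per library (SD, n = 4 each, exact permutation p = 0.0857, two-sided). Mitochondrial ribosomal RNA alone took 72.0% ± 3.84 and 74.9% ± 2.49 of the reads, and the CPM totals include it. Within the 4 numbered pairs the mitochondrial share differed by −6.723 to −0.508 percentage points, and the number of detected genes by 410 to 2136 (exact permutation p = 0.125 each, the smallest that pairs allow). The labels do not say whether the replicates came from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

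The comparison asked how the transcriptome of cells that had cycled after delivery of the cell cycle genes differed from that of cells that had not. Among 12466 tested genes, 309 differed between single and double colored cells, 289 higher and 20 lower in single colored cells (edgeR quasi-likelihood test, adjusted p under 0.05). Of 13 tested lymphocyte genes 10 rose, and of 20 myeloid genes 11 rose and 1 fell, with list medians of 2.76 and 1.11 on the log2 scale. Ctss, a lysosomal protease of antigen-presenting cells, had the smallest p, with a log2 fold change of 2.30 ± 0.21 (SE). All 26 tested fatty acid oxidation genes had negative log2 fold changes, with a median of −0.57, and 1 of them passed the threshold. None of the 4 injected genes, counted at the mouse genes, passed it, and 1, Ccnb1, passed with scaling by library totals alone. For 295 of the 309 the 4 libraries of one group all lay above those of the other, which held for 9.14% of all tested genes against 2.86% by chance. With the replicate block 939 genes differed, 619 higher and 320 lower, including all 309. Leaving out a library moved the count below the 309 by more than 1.5 times in 3 cases, to 191 without double colored replicate 2, 134 without double colored replicate 4 and 142 without single colored replicate 1, and it was 146 without both libraries numbered 1. In the authors' deposited table, none of 15711 genes had an FDR under 0.05 (smallest 0.185) and 1535 had a raw p under 0.05. All 309 genes had a raw p under 0.05 in the authors' deposited table.

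Known from the study rather than from the labels, the injected genes encode the cyclin-dependent kinases Cdk1 and Cdk4 and the cyclins Ccnb1 and Ccnd1. With TMM scaling none of the 4 passed the threshold with edgeR, none had an unadjusted p under 0.05, and none passed with DESeq2. These values are reads assigned to the mouse genes. The sources used here do not say whether transcripts from the adenoviruses were counted among them, so levels of the injected copies are not known. Ccnd1 (ENSMUSG00000070348, mm9 chromosome 7, 152115836 to 152125774) was measured at 16.6 ± 3.57 CPM (read counts scaled to library size) in single and 17.2 ± 2.39 CPM in double colored cells (SD, n = 4), a log2 fold change of −0.06 ± 0.18 (SE; edgeR adjusted p = 0.932). Cdk4 (ENSMUSG00000006728, chromosome 10, 126500590 to 126504976) had a log2 fold change of −0.13 ± 0.24 (edgeR adjusted p = 0.865), and Cdk1 (ENSMUSG00000019942, chromosome 10, 68799383 to 68815686) one of 0.02 ± 0.48 (edgeR adjusted p = 0.991). Ccnb1 (ENSMUSG00000041431, chromosome 13, 101548605 to 101556525) stood at 0.878 ± 0.320 CPM in single and 0.343 ± 0.298 CPM in double colored cells, with a log2 fold change of 1.35 ± 0.66 (edgeR adjusted p = 0.356). Exons of Cdk4 and Ccnd1 overlap genes on the opposite strand over 18.6% and 21.3% of their length, and the strand setting of the counting is not given in the sources used here. With scaling by library totals alone, where the median of all genes shifted by 0.48, Ccnb1 passed (log2 fold change 1.91, adjusted p = 0.0469) and Cdk4 and Ccnd1 had 0.41 and 0.45. Cdk1 had −0.11 with the replicate block.

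Of 32 tested genes of mitosis and cytokinesis, 30 had positive log2 fold changes and none passed the threshold, either over all genes or adjusted over the list alone. At an unadjusted p under 0.05, 9 were higher and 1 lower, and DESeq2 placed 1 higher. The median log2 fold change was 0.54. Cenpe, a kinetochore motor, was measured at 10.5 ± 2.06 CPM in single and 6.26 ± 1.37 CPM in double colored cells (edgeR adjusted p = 0.0698), and the cyclin Ccna2 at 4.21 ± 0.882 and 2.11 ± 1.03 CPM (adjusted p = 0.145). Bub1, a spindle checkpoint kinase, had a log2 fold change of 0.98 ± 0.34, whereas Cenpf, another kinetochore gene, had one of −0.49 ± 0.16 (adjusted p = 0.174 and 0.151). The list ranked higher than other genes by camera with a preset correlation (adjusted p = 0.000121), with adjusted p = 0.372 with an estimated correlation and 0.314 with the filter at 5 CPM. Of 27 tested DNA replication genes, none passed the threshold over all genes and 2 did adjusted over the list alone, against 5 at an unadjusted p under 0.05 and 1 with DESeq2. Their median was 0.19, with the replication complex gene Gins2 at 2.01 ± 0.57 (adjusted p = 0.0810), Mcm6 at 0.84 ± 0.25 (0.0944), Mcm5 at 1.60 ± 0.53 (0.146) and the licensing factor Cdt1 at 1.59 ± 0.54 (0.152). Exons of Gins2 overlap Gse1 on the opposite strand over 67.3% of their length. The replication list ranked higher by camera (adjusted p = 0.0239, and adjusted p = 0.433 with an estimated correlation). Without double colored replicate 2 or single colored replicate 1 its camera adjusted p was 0.0697 and 0.181, and it was 0.208 with scaling by totals alone. Its median was 0.12 and 0.01 without these 2 libraries, and 0.32 and 0.33 without double colored replicate 1 or single colored replicate 3. With the replicate number as a block, 2 mitosis genes were higher, Cenpe (edgeR adjusted p = 0.00936) and Ccna2 (0.0131), as were 4 replication genes, among them Mcm6 (0.0285), Mcm5 (0.0313) and Gins2 (0.0445). With scaling by totals alone, where all genes shifted by 0.48, Cenpe passed at 1.26 (adjusted p = 0.00197), Ccna2 at 1.49 (0.00346), Bub1 at 1.46 (0.0217), Gins2 at 2.51 (0.00572), Mcm6 at 1.36 (0.00488), Mcm5 at 2.13 (0.00525) and Cdt1 at 2.06 (0.0176). With no filter Cenpe (0.0129), Ccna2 (0.0160), Mcm5 (0.0206) and Gins2 (0.0438) passed, with DESeq2 Cenpe (0.0285) and Gins2 (0.0311), and on the deposited CPM Cenpe (0.0215), Gins2 (0.0330), Mcm5 (0.0332) and Mcm6 (0.0499). The leukocyte genes described next were higher in the same libraries, with a lymphocyte list median of 2.76.

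Among called genes with no overlap between groups, predicted genes and small RNAs left out, the 12 with the largest fold changes upward had low counts in double colored cells. Acp5 (ENSMUSG00000001348, chromosome 9, 21931175 to 21940190), which encodes an acid phosphatase of osteoclasts and macrophages, was measured at 1.05 ± 0.602 CPM in single and 0.0317 ± 0.0402 CPM in double colored cells (edgeR adjusted p = 0.00382). It had 3 reads in all double colored libraries together, so that its ratio of 33.5 has a 95% counting interval of 11.2 to 164. Dhrs9 had 2 such reads and a ratio of 33.9 with an interval of 9.12 to 284. These intervals cover counting error only. Il18rap, a subunit of the interleukin 18 receptor, had a log2 fold change of 3.55 ± 0.54, the T cell receptor chain gene Cd3g one of 3.60 ± 0.76, and Kynu, an enzyme of tryptophan breakdown, one of 4.42 ± 0.79 (adjusted p = 0.00272, 0.0172 and 0.00656). Tarm1 (4.79), Hp, which encodes haptoglobin (3.84), Gpr39 (3.71), Cdh1, which encodes E-cadherin (3.66), and Stra6l (3.62) were also higher by log2 fold change. So were Col24a1, a collagen (3.96 ± 0.61, adjusted p = 0.00287), and Cemip, a gene of hyaluronan breakdown (3.73 ± 0.51, adjusted p = 0.00169). Exons of Gpr39 overlap Lypd1 on the opposite strand over 39.9% of their length. When each library was left out in turn, 9 of these 12 genes kept an adjusted p under 0.05 each time. Gpr39 lost it without double colored replicate 1 or 4 or single colored replicate 4 (adjusted p up to 0.0627), Stra6l without double colored replicate 1, 3 or 4 or single colored replicate 1 or 4 (up to 0.134), and Cd3g without double colored replicate 1, 2 or 4 or single colored replicate 1 (up to 0.0853). Cdh1 lost it without both libraries numbered 1 (0.0583). None of the 12 was kept by the filter at 5 CPM, so none was tested there.

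Genes of macrophages and other myeloid cells rose in 11 of 20 cases. Ctss, a lysosomal protease of antigen-presenting cells (ENSMUSG00000038642, chromosome 3, 95330708 to 95360325), rose from 14.2 ± 3.74 to 70.0 ± 17.4 CPM (SD, n = 4; log2 fold change 2.30 ± 0.21, edgeR adjusted p = 8.05e-05). The integrin genes Itgam (ENSMUSG00000030786, chromosome 7, 135206154 to 135271674) and Itgb2 had log2 fold changes of 1.52 ± 0.16 and 1.88 ± 0.25, and Ptprc, the pan-leukocyte antigen CD45, one of 1.56 ± 0.26 (adjusted p = 0.000259, 0.00107 and 0.00583). Of 20 tested members of the list, 11 rose and 1, the scavenger receptor gene Cd163, fell, with 16 and 2 adjusted over the list alone. Cd163 was named after its values were seen, with a log2 fold change of −1.47 ± 0.33 (edgeR adjusted p = 0.0240). The median of the list was 1.11 (camera adjusted p = 1.62e-15, and adjusted p = 0.265 with an estimated correlation). By fry, which tests whether a list moves one way on balance, the adjusted p was 0.0141. Its mean log2 expression was higher in single colored cells by 0.95 ± 0.19 (exact permutation test, two-sided, p = 0.0286, the smallest that 70 groupings allow; 0.110 adjusted over 23 lists; 0.125 within the numbered pairs, the smallest they allow), with all 4 single colored libraries above all 4 double colored ones.

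Lymphocyte genes showed the largest list median, 2.76. All 13 tested members had positive log2 fold changes, 10 rose, and all 13 did so adjusted over the list alone. Cd3e, a T cell receptor chain, rose from 1.24 ± 0.747 to 7.17 ± 2.88 CPM (log2 fold change 2.53 ± 0.38, edgeR adjusted p = 0.00272). Nkg7, of cytotoxic granules, changed by 3.40 ± 0.52, the interleukin 7 receptor gene Il7r by 2.77 ± 0.45 and the helper T cell coreceptor gene Cd4 by 2.73 ± 0.50 (adjusted p = 0.00272, 0.00365 and 0.00868). Camera gave an adjusted p of 1.61e-17, and adjusted p = 0.118 with an estimated correlation, while fry gave 0.00728. The mean log2 expression of the list was higher by 2.48 ± 0.37 (exact permutation p = 0.0286, two-sided, 0.110 adjusted, 0.125 within pairs). The 8 genes of both lists named here kept an adjusted p under 0.05 when each library was left out in turn. With the filter at 5 CPM too few lymphocyte genes were kept to test the list.

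**Figure D1:**
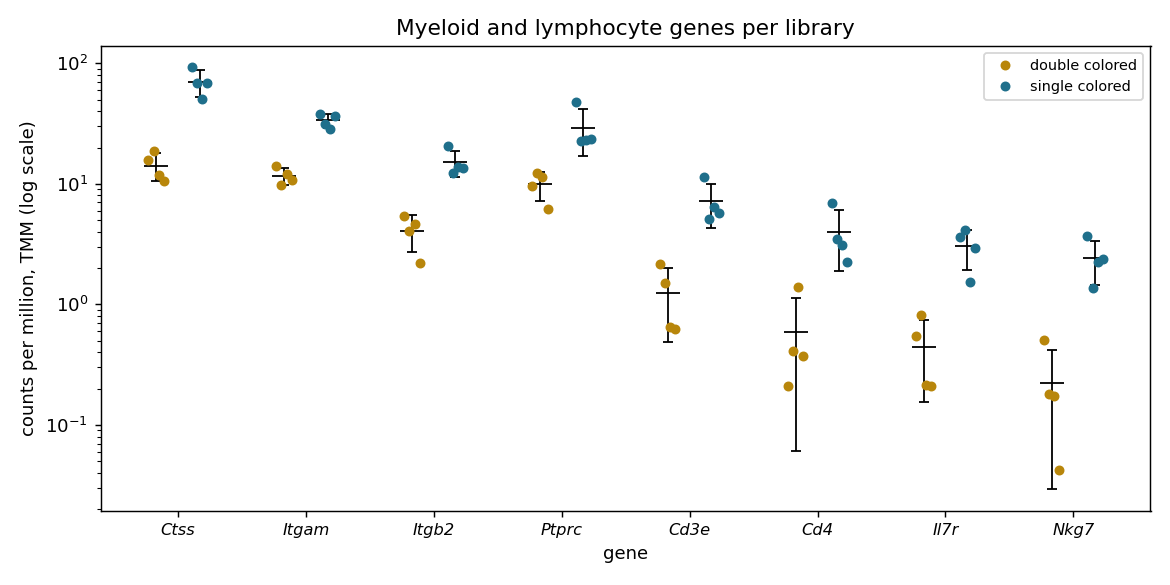
CPM (TMM-scaled, log axis) of 4 myeloid and 4 lymphocyte genes in each library, double colored in gold and single colored in blue, with the horizontal mark at the mean and bars of 1 SD (n = 4). For each gene the 4 single colored libraries lie above the 4 double colored ones, as for Ctss with means of 70.0 and 14.2.

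All 24 tested interferon response genes had positive log2 fold changes, with a median of 0.71. Oasl2, of the antiviral oligoadenylate synthetase family, rose from 22.6 ± 4.80 to 41.4 ± 10.6 CPM (log2 fold change 0.88 ± 0.20, edgeR adjusted p = 0.0262), and Ifih1, a sensor of viral RNA, by 0.74 ± 0.17 (adjusted p = 0.0297). These were the 2 genes past the threshold over all genes, and 13 passed adjusted over the list alone. Ifi44 and Stat2 had log2 fold changes of 0.75 ± 0.19 and 0.72 ± 0.19 (adjusted p = 0.0503 and 0.0562), and with the replicate block 14 members were higher, both among them (0.00466 and 0.00203). Both also passed with DESeq2 (0.0186 and 0.0232), with no filter, with scaling by totals alone and on the deposited CPM. Ifi44 passed after thinning and without mitochondrially encoded genes, and Stat2 with the covariate and without single colored replicate 2 (0.0277). Camera gave adjusted p = 2.91e-12, and adjusted p = 0.372 with an estimated correlation. Oasl2 lost its call without double colored replicate 1, 2 or 4 or single colored replicate 1 or 4 (adjusted p up to 0.0958), and Ifih1 in 7 of 8 omissions, all but that of single colored replicate 2 (up to 0.112). Both calls were also lost with limma-voom and quality weights, as was that of Slc7a11 described next. Of 19 tested genes of the unfolded protein and integrated stress response, Slc7a11, a cystine transporter, rose (log2 fold change 2.76 ± 0.62, edgeR adjusted p = 0.0249), with 2 past the threshold adjusted over the list alone and 2 with the replicate block. It lost its call without double colored replicate 1, 2 or 4 or single colored replicate 1 or 4 (adjusted p up to 0.131). Psat1, a serine synthesis enzyme, had a log2 fold change of 1.01 ± 0.26 (adjusted p = 0.0503, 0.0224 with the block), Sdf2l1 1.25 ± 0.42 (0.148) and Mthfd2 1.17 ± 0.43 (0.193). All 3 passed with scaling by totals alone, and Psat1 also with DESeq2 (0.0160), with no filter, on the deposited CPM and without single colored replicate 3 (0.0339). The stress list median was 0.26, and camera gave an adjusted p of 0.0266, with adjusted p = 0.329 with an estimated correlation, 0.0846 with the replicate block, 0.0956 after thinning to equal nuclear-encoded reads, and 0.113, 0.0551 and 0.0584 without double colored replicate 1, single colored replicate 3 or single colored replicate 4. Without double colored replicate 3 its median was 0.40. With the filter at 5 CPM its median was −0.11 (camera adjusted p = 0.751). By fry the adjusted p was 0.00728. In the same libraries the macrophage list had a median of 1.11 and the lymphocyte list one of 2.76.

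Matrix and fibroblast genes were higher in part. Of 24 tested members 4 rose, over all genes and adjusted over the list alone, and with the replicate block 12 were higher and 1 lower. Timp1, an inhibitor of matrix proteases, rose by 1.88 ± 0.31 on the log2 scale (edgeR adjusted p = 0.00396) and kept its call whichever library was left out. Fn1, which encodes fibronectin, was measured at 267 ± 115 CPM in single and 77.9 ± 37.9 CPM in double colored cells (log2 fold change 1.78 ± 0.38, adjusted p = 0.0374), and the collagen Col1a1 at 288 ± 138 and 84.9 ± 39.5 CPM (1.76 ± 0.40, adjusted p = 0.0460). Thy1, a surface antigen of fibroblasts and T cells, rose by 1.14 ± 0.27 (adjusted p = 0.0345). Fn1 lost its call without double colored replicate 2 or 3 or single colored replicate 1 or 2 (adjusted p up to 0.293), Col1a1 without these or single colored replicate 3 (up to 0.286), and Thy1 without double colored replicate 2, 3 or 4 or single colored replicate 1 or 3 (up to 0.119). All 3 calls were also lost with the filter at 5 CPM, those of Fn1 and Col1a1 with upper-quartile scaling, and that of Col1a1 without mitochondrially encoded genes and after thinning. The list median was 0.54, or 0.19 without single colored replicate 1 (camera adjusted p = 9.79e-06, 0.00283 without that library, and adjusted p = 0.444 with an estimated correlation). Among 15 fetal and dedifferentiation genes, Runx1, a transcription factor, rose by 1.22 ± 0.27 (edgeR adjusted p = 0.0237), a call lost without double colored replicate 1, 2 or 4 or single colored replicate 1 (up to 0.0987). The fetal myosin gene Myh7 (0.79 ± 0.26), Ankrd1 (0.56 ± 0.22) and Vim (0.40 ± 0.21) had adjusted p of 0.155, 0.233 and 0.389, and Vim passed with the replicate block (0.0439). All 3 passed with scaling by totals alone (0.00179, 0.00455 and 0.0166), Myh7 and Ankrd1 on the deposited CPM (0.0201 and 0.0422), and Myh7 with no filter (0.000550). The fetal list median was 0.31, or 0.19 without double colored replicate 3 and 0.16 without single colored replicate 2 (camera adjusted p = 0.00348, adjusted p = 0.433 with an estimated correlation, and 0.529 without double colored replicate 3). Of 9 epicardial genes none passed with edgeR or DESeq2, against 2 at an unadjusted p under 0.05. Among them were Krt18 (2.24 ± 0.80, edgeR adjusted p = 0.182, 0.0475 with the block, and also passed with no filter, with scaling by totals alone and on the deposited CPM), Upk1b (1.60 ± 0.72), Lrrn4 (0.95 ± 0.56) and Msln (1.11 ± 0.67). The epicardial median was 0.95, or 0.54 without double colored replicate 4 (camera adjusted p = 0.00100, and adjusted p = 0.372 with an estimated correlation). The lymphocyte list median in the same libraries was 2.76.

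Of the genes of fatty acid oxidation, the main fuel pathway of adult heart muscle, all 26 tested members had negative log2 fold changes, with a median of −0.57, and 1 passed the threshold over all genes. This was Hadh, an enzyme of the beta-oxidation cycle (ENSMUSG00000027984, chromosome 3, 130936337 to 130975019), which fell from 35.6 ± 3.06 CPM in double to 21.8 ± 5.79 CPM in single colored cells (log2 fold change −0.71 ± 0.18, edgeR adjusted p = 0.0491, 0.00301 with the block). Hadh lost its call in 7 of 8 omissions of a library, all but that of single colored replicate 2 (adjusted p up to 0.149). Adjusted over the list alone 17 were lower, and with the replicate block 18. Ppargc1a, a coactivator of mitochondrial gene expression, had a log2 fold change of −0.60 ± 0.17, Decr1 −0.77 ± 0.21 and Mlycd −0.84 ± 0.22 (adjusted p = 0.0737, 0.0738 and 0.0526, and 0.00366, 0.00203 and 0.0207 with the block). All 3 passed with DESeq2 (0.0181, 0.0241 and 0.0165) and with no filter. Ppargc1a also passed without both libraries numbered 1, and Mlycd with upper-quartile scaling, after thinning and without single colored replicate 3 (0.0462). Camera gave an adjusted p of 1.62e-15, and adjusted p = 0.372 with an estimated correlation, while fry gave 0.138. The mean log2 expression of the list was lower by −0.63 ± 0.25 (exact permutation p = 0.0286, two-sided, 0.110 adjusted, 0.125 within pairs). Single colored replicate 1 had the lowest value, 3.78, against 4.65 to 4.82 in the other single colored libraries. Without it the list median was −0.37 (camera adjusted p = 2.16e-15).

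All 36 tested nuclear genes of oxidative phosphorylation had negative log2 fold changes with a median of −0.40. None passed over all genes or over the list alone, 16 were lower at an unadjusted p under 0.05, 2 with DESeq2 and 7 with the replicate block. Cox7b (−0.56 ± 0.16), Cycs, which encodes cytochrome c (−0.81 ± 0.24), Cyc1 (−0.49 ± 0.19) and Atp5c1 (−0.45 ± 0.18) had edgeR adjusted p of 0.0863, 0.0989, 0.209 and 0.221, and of 0.0106, 0.0456, 0.0154 and 0.0362 with the block. Cox7b and Cycs passed with DESeq2 (0.0115 and 0.0493), and Cox7b with no filter and with voom and quality weights. Camera gave an adjusted p of 2.06e-14, and adjusted p = 0.372 with an estimated correlation. Single colored replicate 1 scored 4.66, against 5.39 to 5.59 in the other single colored libraries, and without it the median was −0.23 (camera adjusted p = 3.70e-11). The 8 tested mitochondrially encoded genes had a median of −0.59. None passed over all genes, all 8 did adjusted over the list alone and at an unadjusted p under 0.05, 3 did with DESeq2 and 5 with the block. Among them mt-Co1 (−0.62 ± 0.23, adjusted p = 0.190, 0.0459 with the block), mt-Nd1 (−0.63 ± 0.24, 0.0348 with the block), mt-Nd2 (−0.60 ± 0.23, 0.0305) and mt-Cytb (−0.59 ± 0.23, 0.0496) had the smallest p (camera adjusted p = 0.000270 for the list, and adjusted p = 0.386 with an estimated correlation). Sarcomere genes, which build the contractile apparatus, had negative values in 23 of 25 cases with a median of −0.33. None passed with edgeR or DESeq2, and 3 were lower at an unadjusted p under 0.05. Tnni3 (−0.53 ± 0.21), Myl2 (−0.47 ± 0.21), Ckm (−0.45 ± 0.21) and Myot (−0.53 ± 0.25) had adjusted p between 0.230 and 0.332, and Tnni3 passed with the block (0.0423). Camera gave adjusted p = 7.92e-07, and adjusted p = 0.433 with an estimated correlation. The sarcomere score of single colored replicate 1 was 7.16, against 7.92 to 8.11 in the other single colored libraries, and without it the median was −0.16 (camera adjusted p = 0.000208). Exons of Ckm overlap A930016O22Rik on the opposite strand over 31.9% of their length. The lymphocyte list median of 2.76 was measured in the same libraries.

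Of 24 calcium handling and ion channel genes, all had negative log2 fold changes, with a median of −0.34. Kcnj3, a subunit of the acetylcholine-gated potassium channel, fell from 10.5 ± 1.56 to 5.58 ± 1.64 CPM (log2 fold change −0.91 ± 0.22, edgeR adjusted p = 0.0351), the one member past the threshold over all genes and over the list alone, against 5 with the block. Kcnd2 (−0.64 ± 0.23), the calcium pump regulator Pln (−0.53 ± 0.20) and Trdn (−0.38 ± 0.15) had adjusted p of 0.186, 0.218 and 0.224, and Kcnd2 and Pln passed with the block (0.0439 and 0.0366). Camera gave adjusted p = 5.75e-09, and adjusted p = 0.372 with an estimated correlation. The list score of single colored replicate 1 was 4.85, against 5.43 to 5.65 in the other single colored libraries, and without it the median was −0.21 (camera adjusted p = 9.99e-07). With all libraries the lymphocyte list median was 2.76 and that of the myeloid list 1.11. Among called genes with no overlap between groups, predicted genes left out, the largest decreases were in Usp49, a deubiquitinase (−1.29 ± 0.29, adjusted p = 0.0238), Lonrf2 (−1.29 ± 0.30, 0.0307), and Gpr22, a receptor of heart and brain (ENSMUSG00000044067, chromosome 12, 32391732 to 32398812; −1.27 ± 0.25, 0.0121), followed by Pirt (−1.23 ± 0.26, 0.0170) and Amigo1 (−0.999 ± 0.25, 0.0437). Usp49 shares 51.2% of its exon length with Gm20517 on the same strand, and Kcnj3 overlaps an unnamed antisense gene over 31.1%. Mkks (−0.90), Atp5s (−0.88), the calcium-dependent kinase gene Camk2a (−0.83), the homeodomain gene Hopx (−0.78) and Corin, the protease that activates natriuretic peptide (−0.67 ± 0.17, adjusted p = 0.0474), were also lower. With Kcnj3 and Hadh, these 12 genes kept their call in part when a library was left out. Of them 5, 3, 4 and 1 passed without double colored replicates 1 to 4, and 3, 6, 10 and 5 without single colored replicates 1 to 4, with adjusted p up to 0.163 and no change of sign. With scaling by totals alone or on the deposited CPM, Gpr22 alone of the 12 passed. Calls were also lost for Kcnj3, Hadh and Corin with the 5 CPM filter, Amigo1, Hadh and Corin with voom, Hadh and Corin with the non-robust fit, Atp5s, Hadh and Corin with the covariate, and Lonrf2, Amigo1 and Mkks after thinning. The number of genes lower was 11, 7, 9 and 1 without double colored replicates 1 to 4, and 8 and 13 without single colored replicates 1 and 4, against 20 with all libraries. Where libraries were scaled by their totals alone, the median of all genes shifted by 0.48, 1 gene was lower, and the medians became 0.14 for sarcomere, 0.12 for calcium handling and 0.05 for nuclear oxidative phosphorylation genes, lower only relative to that shift. Those of fatty acid oxidation and mitochondrially encoded genes were −0.11 and −0.16.

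**Figure D2:**
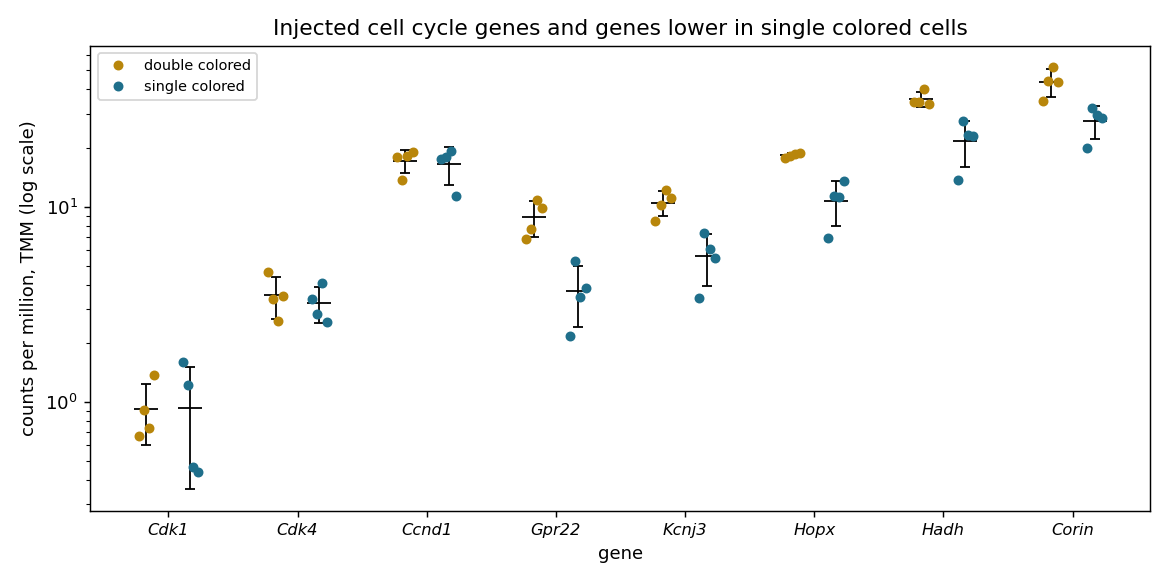
CPM (TMM-scaled, log axis) of 3 injected cell cycle genes (reads counted at the mouse genes) and 5 genes lower in single colored cells, per library, double colored in gold and single colored in blue, with the mean and bars of 1 SD (n = 4). Ccnb1 is not drawn because 1 library had 0 reads; Cdk1, Cdk4 and Ccnd1 overlap between groups, and Hadh had means of 35.6 and 21.8.

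Of 21 glycolysis genes none passed over all genes, against 2 higher and 5 lower at an unadjusted p under 0.05 and 1 and 1 with DESeq2. Adjusted over the list alone 1 was higher, the phosphofructokinase Pfkp (0.65 ± 0.17, edgeR adjusted p = 0.0600 over all genes and 0.00836 with the block), and 1 was lower. With the replicate block 1 was higher and 5 were lower, among them Eno3 (−0.65 ± 0.20, 0.109, and 0.0104 with the block), Pfkm (−0.56 ± 0.20, 0.175 and 0.00998) and the glucose transporter Slc2a4 (−0.56 ± 0.22, 0.218 and 0.0336). Pfkp also passed with DESeq2 (0.0241), with no filter, the covariate, scaling by totals alone, on the deposited CPM and without double colored replicate 2 (0.0208). Eno3 passed with DESeq2 (0.0352), with no filter and without single colored replicate 1 (0.0498), and Pfkm with no filter. The glycolysis median was −0.07 (camera adjusted p = 0.104, 0.0469 with the block, 0.0360 with no filter, 0.0197 and 0.0405 without single colored replicate 3 or 4). Of 22 immediate early genes 19 had negative log2 fold changes, and none passed with edgeR or DESeq2. At an unadjusted p under 0.05, 1 was higher and 10 were lower, and 4 were lower with the block, with Atf3 at −0.68 ± 0.21 (adjusted p = 0.122, 0.0142 with the block), Klf2 at −0.53 ± 0.18 (0.152 and 0.0335), Klf4 at −0.56 ± 0.21 (0.195 and 0.0229) and Nr4a1 at −0.59 ± 0.22 (0.207 and 0.0117). With no filter Atf3, Klf4 and Nr4a1 passed, and Atf3 also without double colored replicate 1 (0.0379). Their median was −0.36, or −0.21 without double colored replicate 3 and 0.07 with scaling by totals alone (camera adjusted p = 0.000253, and adjusted p = 0.386 with an estimated correlation). Of 20 endothelial genes 17 had negative log2 fold changes and none passed, against 1 higher and 3 lower at an unadjusted p under 0.05 and 1 lower with DESeq2. One was higher, Vwf (0.62 ± 0.26, adjusted p = 0.254, 0.0105 with the block), and 1 lower, Fabp4 (−0.53 ± 0.16, 0.117 and 0.0152), with the replicate block. Vwf also passed with no filter (0.0398) and with scaling by totals alone (0.00848), and Fabp4 with DESeq2 (0.0465). Robo4 (−0.38 ± 0.17) and Cav1 (−0.39 ± 0.18) had adjusted p of 0.299 and 0.306. The changes of these 3 lists were measured beside lymphocyte and myeloid list medians of 2.76 and 1.11 in the same libraries. The endothelial median was −0.19, or −0.12 without single colored replicate 3 and 0.26 with scaling by totals alone, where camera gave 0.450 (camera adjusted p = 0.0123, and adjusted p = 0.480 with an estimated correlation; 0.0795, 0.0605 and 0.119 without double colored replicate 1 or 4 or single colored replicate 3, 0.158 with the filter at 5 CPM and 0.165 on the deposited CPM).

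Besides glycolysis, lists without a call by camera were the 9 cell cycle inhibitors, 18 p53 targets, 13 smooth muscle genes, 6 erythroid genes, 35 ribosomal protein genes and the 4 injected genes. With TMM scaling these 6 lists had no member past the threshold with edgeR, over all genes or over the list alone, or with DESeq2. At an unadjusted p under 0.05 there were 1 higher inhibitor, 1 higher and 1 lower p53 target, 2 lower smooth muscle genes and no others. Their medians were −0.16, 0.16, 0.05, 0.03, 0.01 and −0.02. The camera direction was up for the inhibitors and the injected genes and down for smooth muscle, opposite to these medians. Cdkn1a, the inhibitor p21, had a log2 fold change of 0.25 ± 0.15 (edgeR adjusted p = 0.458), Rbl1 0.82 ± 0.32, Rb1 0.21 ± 0.16 and Meis1 −0.36 ± 0.24. Among p53 targets Btg2, an antiproliferative gene, had −0.50 ± 0.19 (adjusted p = 0.201, 0.0134 with the block), Zmat3 0.37 ± 0.17, Rrm2b −0.42 ± 0.21 and Ccng1 −0.34 ± 0.18. Abcc9, a potassium channel subunit on the smooth muscle list, had −0.59 ± 0.20 (0.145, and 0.00605 with the block), beside Rgs5 at −0.40 ± 0.18, Cald1 at 0.37 ± 0.21 and Acta2 at 0.31 ± 0.20. With no filter Abcc9 passed (0.0294), as it did without both libraries numbered 1. With scaling by totals alone, where all genes shifted by 0.48, Cdkn1a (0.0485), Rbl1 (0.0197), Zmat3 (0.0262), Cald1 (0.0218) and Acta2 (0.0350) passed. The globin genes Hba-a1 (0.61 ± 1.24) and Hbb-bt (0.35 ± 1.05), whose reads can be shared with near-identical copies, and Alas2 (−0.09 ± 0.58) varied widely, and Bpgm had −0.02 ± 0.25. Without double colored replicate 1 the erythroid median was 2.17 (camera adjusted p = 0.000129) and Hba-a1 passed (3.99, adjusted p = 0.00838). The ribosomal protein genes Rpl3 (0.58 ± 0.34), Rps3 (0.19 ± 0.13), Rps7 (0.53 ± 0.41) and Rps13 (0.45 ± 0.51), which have many processed copies in the genome, had adjusted p between 0.452 and 0.751. In all, camera placed 9 lists higher and 7 lower, and 8 and 8 with the replicate block. No list passed with an estimated correlation, and fry placed 3 higher and 0 lower. The other ways of splitting the 8 libraries into 4 and 4 gave up to 17 lists by camera with the preset correlation.

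**Figure D3:**
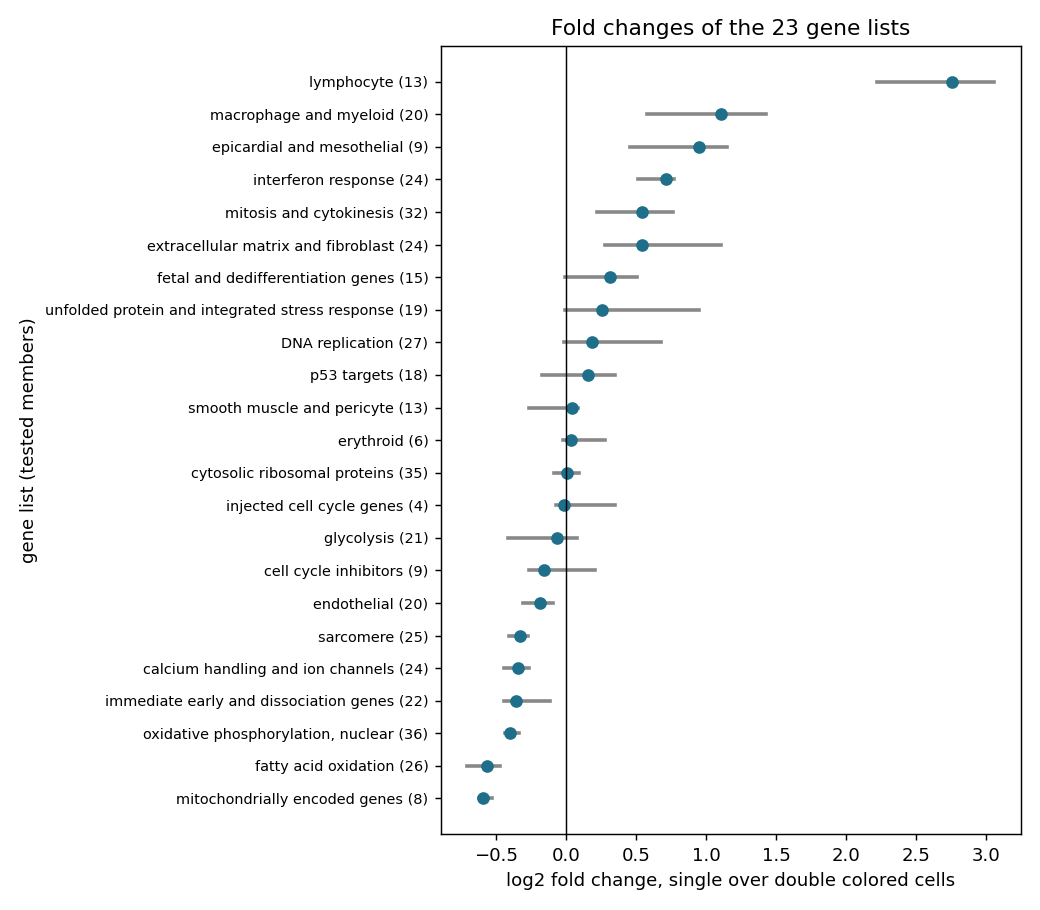
Median log2 fold change, single over double colored cells (points), with the interquartile range over members (bars), for the 23 gene lists with their number of tested members. Medians run from −0.59 for mitochondrially encoded genes to 2.76 for lymphocyte genes.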

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

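Chosen after the results were seen were the tests on leukocyte genes and on the dilution of fatty acid oxidation genes, and the values within numbered pairs. Thinning was added after the data were seen.

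Most changed genes were higher in single colored cells, 289 of 309 (93.5%), against 65.9% of 939 with the replicate block and 79.8% of 805 with no filter. Of the 35 ways to split the 8 libraries into 4 and 4, the real one alone (1 split) gave as many changed genes (309, highest other 17), as many higher (289, highest other 14) and as many lower (20, highest other 14), while 2 splits gave as many lists as the 16 past the threshold (highest other 17). With the numbers taken as pairs, the 8 splits that part all 4 pairs, unlike the other 27, are too few for a share under 0.05 (309 changed genes for the real one, highest other 0). After thinning to equal nuclear-encoded reads 92.6% of the changed genes were higher, which argues against a difference in depth as the cause of the direction. Scaling stays open: under 3 other scalings at least 91.8% were higher, but none lowered the median of all genes by over 0.1 (−0.015 to 0.484), so none could have lowered the share much.

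Of the lymphocyte and myeloid lists 10 of 13 and 11 of 20 genes rose in single colored cells. The lymphocyte score rose by 2.638 ± 0.425 (SE) more than the endothelial score, and by 1.864 to 3.477 in the 4 numbered pairs. The exact permutation test, two-sided, gave p = 0.0286 over all groupings and 0.125 within pairs, the smallest each allows. This contrast was chosen after both list results were seen, so its p-values are no independent test of a lower share of cardiomyocyte RNA that raises every other cell type alike. The values show only that these 2 lists did not rise alike, with the endothelial score changed by −0.155 ± 0.119 (SE). Of 9 tested resident macrophage markers 1 had a positive log2 fold change, 0 were higher and 1 was lower. Their median was −0.81 and their score changed by −0.703 ± 0.203 (SE). Markers of monocyte-derived cells (9 of 9 higher, median 1.85) rose by 2.536 ± 0.341 more than those of resident macrophages. This difference was 1.784 to 3.119 in the pairs (exact permutation p = 0.0286, 0.125 within pairs). Both lists were drawn up after the results were seen, so it does not decide whether the resident population was larger. A candidate explanation that stays open is T cells and monocyte-derived cells, or their RNA, among the collected single colored cells, with 19 of 19 pan-leukocyte genes positive, 14 higher and a median of 1.326; Ctss reached 70.0 CPM and Ptprc 29.2 CPM. The pan-leukocyte list was also drawn up after the lymphocyte and myeloid results were seen. Its rise is therefore no independent test of this candidate. The 3 added lists share 2, 3 and 2 genes with the myeloid list, and the labels describe no sort or gate that would remove leukocytes.

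All 26 fatty acid oxidation genes had negative log2 fold changes, 1 passed the threshold (Hadh, adjusted p = 0.0491, lost in 7 of 8 omissions of a library), and the list did not pass with fry (adjusted p = 0.138) or with an estimated correlation (adjusted p = 0.372). Their score changed by −0.272 ± 0.065 (SE) more than the sarcomere score, and by −0.419 to −0.132 in the 4 numbered pairs. The exact permutation test, two-sided, gave p = 0.0286 over all groupings and 0.125 within pairs, the smallest each allows. This contrast was chosen after both list results were seen. It therefore does not decide whether dilution of cardiomyocyte RNA by RNA of other cells was the whole cause. The sarcomere score itself changed by −0.354, against −0.404 for calcium handling and −0.433 for nuclear oxidative phosphorylation genes. Neither of these 2 lists was set against the fatty acid oxidation list. Dilution may account for a part or all of the decrease, since sarcomere genes also had a negative median, −0.33. The difference in cell cycle history that the labels name stays open and untested.

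Of 284 groups of 4 values, 19 (6.7%) held a library whose gap to its nearest neighbor exceeded Dixon's 95% critical share of the group's range, where chance gives about 1 in 20. The values that follow are that share, on log2 CPM. In single colored replicate 1 it was 0.837 for the fatty acid oxidation score (3.78 against 4.65 to 4.82), 0.854 for Tnni3, 0.881 for Ppargc1a, 0.931 for Decr1, 0.932 for Eno3 and 0.853 for Abcc9, each the lowest of its group, and 0.939 for Ptprc, the highest. In single colored replicate 2 it was 0.846 for Il18rap and 0.959 for Stat2, both lowest. The lowest values were also those of Krt18 in single colored replicate 3 (0.852) and of the injected gene score in single colored replicate 4 (0.845). In double colored replicate 1, Trdn (0.929) and Klf4 (0.857) were lowest and Alas2 (0.831) highest. Pfkp was highest in double colored replicate 2 (0.876), Hadh (0.868) and Decr1 (0.832) were highest and Cenpe (0.855) lowest in double colored replicate 3, and Cdkn1a was highest in double colored replicate 4 (0.8294).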

How the results depend on the processing

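Chosen after seeing the data were thinning to equal nuclear-encoded reads, restriction to the authors' kept genes, omission of both libraries numbered 1, and the 14 combinations on the authors' genes; in all 39 settings were run. Counts are changed, higher and lower genes, against 309, 289 and 20, with 9 lists higher and 7 lower, and the cause of a change was not tested. Counts stayed within 1.5 times under RLE, upper-quartile, voom with quality weights, the non-robust fit, the covariate, omission of mitochondrial genes, thinning and the authors' genes alone. They were 1390, 1389 and 1 with library totals, 805, 642 and 163 with no filter, 97, 93 and 4 at 5 CPM (4 lists higher), 557, 463 and 94 with DESeq2, 939, 619 and 320 with the replicate block, and 555, 551 and 4 with limma on the deposited CPM. At 5 CPM the lymphocyte, DNA replication, epicardial, erythroid and injected gene lists had too few members left and were not tested. Fry gave 3 lists higher and 0 lower, and camera with an estimated correlation 0 and 0. Without single libraries the counts ran from 134 to 304, 133 to 277 and 1 to 29, with 8 to 9 lists higher and 6 to 8 lower. Without both libraries numbered 1 they were 146, 135 and 11.

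On the authors' genes with library totals, counts were 855, 832 and 23 by the exact test, 951, 920 and 31 by likelihood ratio, 499, 496 and 3 by quasi-likelihood, 1349, 1286 and 63 with the block, 1705, 1600 and 105 by likelihood ratio with the block, 539, 535 and 4 by limma, and 306, 305 and 1 by voom. With TMM they were 567, 489 and 78 by the exact test, 640, 541 and 99 by likelihood ratio, 281, 269 and 12 by quasi-likelihood, 940, 623 and 317 with the block, 1333, 870 and 463 by likelihood ratio with the block, 340, 314 and 26 by limma, and 155, 148 and 7 by voom.

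No called named gene changed sign. Across genes and settings 2220 values kept direction and side of the threshold, 172 lost their call, 125 gained one and 39 changed sign. Lists were judged by their camera call and direction, whatever the sign of the median. By that rule 491 list values stayed the same, 47 lost their call, 6 gained one and 1 turned direction. Medians of some lists changed sign without being counted so. With library totals these included the sarcomere, calcium handling, nuclear oxidative phosphorylation, immediate early and endothelial lists. Beyond the values given with each result, the block changed no other call that the report names. Signs changed for uncalled genes. With library totals, which shift the median of all genes by 0.48, log2 fold changes were 0.41 for Cdk4, 0.45 for Ccnd1, 0.09 for Meis1, 0.04 for Rrm2b, 0.12 for Ccng1, 0.01 for Ckm, 0.08 for Trdn, 0.11 for Robo4, 0.07 for Cav1, 0.06 for Rgs5, 0.45 for Alas2 and 0.44 for Bpgm. On the deposited CPM they were 0.08 for Cdk4, 0.14 for Ccnd1, 0.11 for Alas2 and 0.21 for Bpgm. Bpgm had 0.02 at 5 CPM and 0.03 with voom. Cdk1 had −0.13 with voom and −0.11 with the block and after thinning. The stress response median was −0.11 at 5 CPM. Leaving out single libraries or both numbered 1, values ran from −0.51 to 0.27 for Cdk1, −0.28 to 0.03 for Cdk4, −0.15 to 0.08 for Ccnd1, −0.42 to 2.40 for Hbb-bt and −0.49 to 0.85 for Alas2, and the log2 fold change of Bpgm ran from −0.20 to 0.37. Depth limits the ratios of genes with few reads, as for Acp5 with 3 reads in double colored cells (ratio 33.5, 95% counting interval 11.2 to 164).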

Other observations

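All genes in this part were chosen after their values were seen, and no list of them was tested. Tnc, which encodes tenascin C, was measured at 21.3 ± 9.01 CPM in single and 5.39 ± 2.06 CPM in double colored cells (SD, n = 4; log2 fold change 1.99 ± 0.29, edgeR adjusted p = 0.00272). The collagen Col11a1 had a log2 fold change of 2.99 ± 0.46 (adjusted p = 0.00360), Tgfbi 1.71 ± 0.24 (0.00169), Runx2, a transcription factor of bone formation, 2.13 ± 0.35 (0.00407), and Thbs1, which encodes thrombospondin 1, 1.07 ± 0.18 (0.00490). Nrg1, which encodes the growth factor neuregulin 1, had 2.43 ± 0.48 (0.0124).

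Cd74, the invariant chain of class II antigen presentation, was measured at 98.3 ± 23.1 CPM in single and 37.3 ± 17.1 CPM in double colored cells (SD, n = 4; log2 fold change 1.40 ± 0.28, edgeR adjusted p = 0.0150). H2-Ab1 had 1.44 ± 0.27 (0.0117), H2-Aa 1.47 ± 0.29 (0.0182), and Ciita, their transcriptional activator, 1.35 ± 0.32 (0.0320).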
